A study of Ascaris suum with 10 samples.

How the data were processed

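Polyadenylated RNA of the pig roundworm Ascaris suum, a parasitic nematode, was sequenced in 10 libraries. The labels list embryos incubated for 24, 46 and 64 hr, second-stage larvae of day 7, the germinal zones of testis and ovary, intestine, muscle with hypodermis, and male and female carcass (muscle, hypodermis, pharynx and neurons). Per the labels' protocols, RNA was fragmented, copied with random primers, amplified over 17 PCR cycles and sequenced on Illumina GAII or HiSeq2000 instruments. Which library ran on which instrument is not given in the sources used here.

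The deposited table holds RPKM values (reads scaled by the length of the gene model in kilobases and by the mapped reads of the library, by the name the authors gave the unit) for 15446 genes in 8 columns, with 1 decimal. TopHat and Cufflinks are named in the submitters' processing notes. Cufflinks reports fragments, and whether reads or fragments were counted could not be told from the values. Their versions, the genome build, the annotation, the gene lengths, the strandedness of counting and the read totals are not given in the sources used here. Because 1 read is worth a different RPKM for each gene length and the values are rounded to 0.1, whole reads could not be recovered and the depth is unknown. No interval or detection limit that needs a depth is given, and a value of 0 is called "listed at 0". Only 1 gene was listed at 0 in a column (intestine) while standing at 10 RPKM or more in all the others.

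Columns were assigned to samples by their titles, which matched for 7 columns. The table has a single embryo column for the 3 embryo libraries. Whether it is an average or a pool is not stated, so it is reported as the authors' embryo value, and the planned comparisons of 64 hr with 24 hr, of larva with 64 hr and of 24 hr with ovary were not made. The embryo column was set against ovary and larva in their place, a choice made after seeing the table. The number of columns from outside the series was 0. The table pairs its gene identifiers with no names, and no genome or annotation was used here. The 22 gene lists fixed beforehand (sperm proteins, germ granules, meiosis, muscle, collagens and others) could therefore be matched to no gene, and eliminated and retained genes could not be separated.

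Each stage or tissue has 1 library, so no test across replicates was possible and no p-value is given. Differences were counted by size rules set before the data were examined. A gene was detected at 1 RPKM or more. A pair difference was a log2(RPKM + 1) difference of at least 2, which understates the change of low genes. A gonad-restricted gene had 5 RPKM or more in testis or ovary and under 1 RPKM in all 4 adult somatic libraries. A gonad-enriched gene had a lower gonad value above the highest adult somatic value by at least 2 on that log2 scale. Tissue specificity was the index tau on log2(RPKM + 1) over the 8 columns, which is 0 for even expression and 1 for expression in a single column, with a threshold of 0.9 and a highest value of 5 RPKM or more. The design had named 10 libraries for tau. The male and female carcass libraries, which the labels give the same tissues, served as the only yardstick for how far a pair of libraries of like tissue lie apart. It includes the difference of sex. Identifiers are named by a rule set beforehand, the 2 largest log2 ratios in each direction among genes of 10 RPKM or more in the higher library.

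Genes led by a column were those at 500 RPKM or more there and at most 1/5 of that in every other column (50 RPKM or more for the wider set). Their level in another column was expressed as a percentage of the leading column. After these values were seen, an alternative subtracted from ovary the median percentages of testis and larva, and from larva those of testis and ovary. The ovary percentage in larva was not constant over ovary levels, so that part of the subtraction is the least certain. The alternatives set beforehand were pseudocounts of 0.1 and 5, a minimum of 5 RPKM, log2 thresholds of 1 and 3, other minimum levels, each somatic library left out, and 3 rescalings of the columns (to an equal sum, by the upper quartile, and by the median of ratios over genes above 0 in every column). The arithmetic of the counting rule was tested on simulated data, a pair of copies of the ovary column (15446 genes) with an assumed noise of 0.5 (SD, log2), where it recovered 96% of 100 genes changed 8-fold and 100% of 100 changed 16-fold. That noise is not a measured spread between libraries, so the simulation does not give the rate of false calls. The carcass pair had 924 genes past the threshold. A simulated share of 4% of testis in ovary, with the ovary values of testis-led genes first set to 0, gave a median of 4.02% and a slope of 1.01. Both follow from that setup, and any ovary expression of these genes would raise the median above the share. With the ovary values shuffled over the testis-led genes the median was 3.82% and the slope 0.058, so the median percentage does not by itself tell a fixed share from none. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.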

Results

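Gene expression was profiled by RNA sequencing across the life cycle and adult tissues of Ascaris suum. In this nematode, parts of the germline genome are removed from somatic cells during early cleavage, and the series asked in which tissues each gene is expressed. The deposited table gives 15446 genes in 8 columns, namely testis, ovary, embryo, larva, intestine, muscle, male carcass and female carcass. Each column stands for 1 library except embryo, which stands for 3 (24 hr, 1 cell; 46 hr, 1 to 2 cells; 64 hr, 2 to 4 cells). With 1 library per tissue there is no replicate error, and every difference given here compares these libraries and was not tested across animals. The sums of RPKM over genes ran from 564412 in larva to 821149 in female carcass, and read totals are unknown.

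Larva, embryo and ovary had the most genes detected and intestine the fewest. At 1 RPKM or more, 12541 genes were detected in larva, 12213 in the embryo column, 12211 in ovary, 11675 in male carcass, 11569 in female carcass, 10285 in testis, 9914 in muscle and 8616 in intestine. Of all genes, 6228 were detected in every column and 477 in none. The most abundant transcripts took very different shares of the columns. The 10 highest genes held 34.6% of the summed RPKM in intestine, 29.3% in testis and 20.6% in ovary, but 9.81% in larva and 6.79% in embryo. A single intestinal gene, ASG15439, reached 115894 RPKM, or 16.6% of the intestine sum. The highest testis gene, ASG12930, reached 47009 RPKM.

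**Figure D1:**
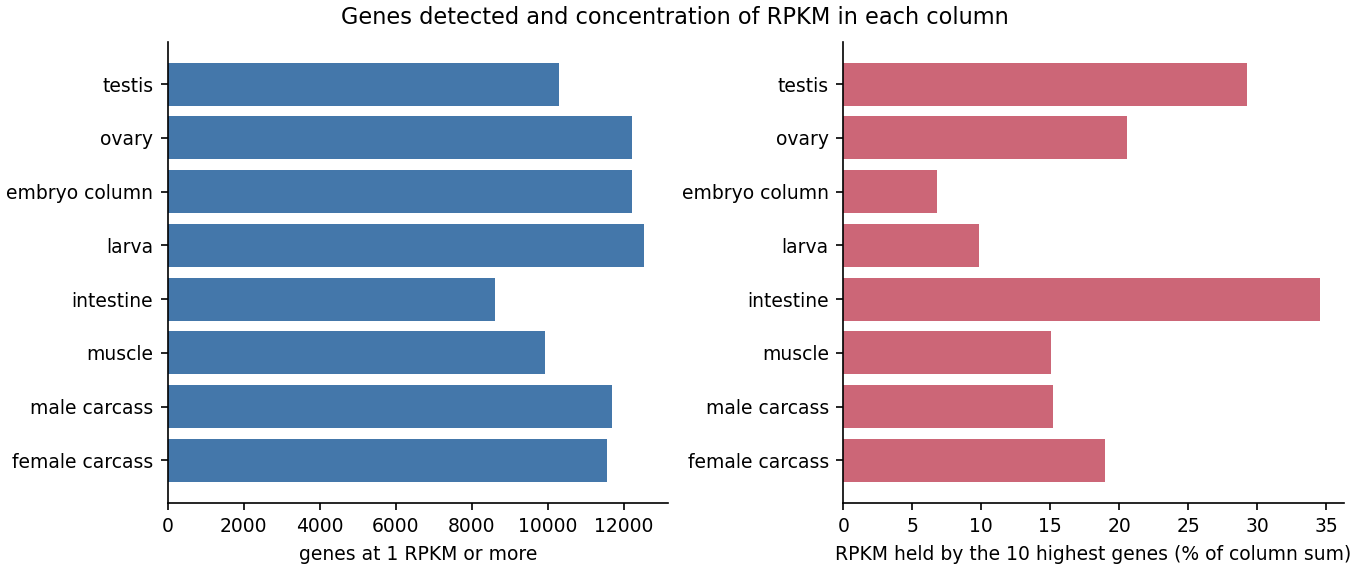
Bars show, for each of the 8 columns, the number of genes at 1 RPKM or more (left) and the percentage of the column's summed RPKM held by its 10 highest genes (right). Intestine has the fewest genes detected (8616) and the highest concentration (34.6%), while the embryo column is the least concentrated (6.79%).

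Across genes, the 3 libraries that contain body-wall muscle were the most alike. Spearman's rho was 0.86 between male and female carcass, 0.85 between muscle and male carcass and 0.86 between muscle and female carcass. Intestine was closest to male carcass (rho 0.68). Ovary was close to embryo (rho 0.78) and to larva (rho 0.77), and testis was closer to ovary (rho 0.64) than to any other column, with its lowest value against muscle (rho 0.27). With the median percentages of led genes subtracted from ovary and larva, rho was 0.65 between ovary and larva and 0.51 between testis and ovary, below the 0.54 between testis and embryo, and it stayed at 0.78 between ovary and embryo. Subtracting part of a column from another tends to lower their correlation by construction, and nothing was subtracted from embryo. The lower values therefore do not place testis nearer to embryo than to ovary. These correlations are across genes, which are not independent replicates.

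Expression restricted to the gonads was the first comparison the design implies. Under the size rule, 885 genes (5.73% of the table) were gonad-restricted, and most were testis genes. Of these, 696 stood at 5 RPKM or more in testis and below that in ovary, 109 in ovary and below that in testis, and 80 in both. The testis group had a median of 35 RPKM in testis, 0.1 in intestine, 0 in muscle, 0.3 in male carcass and 0 in female carcass. Of the 6593 genes at 5 RPKM or more in testis, 11.8% were gonad-restricted, against 2.17% of the 8722 genes at that level in ovary. The 2 largest ratios belonged to ovary genes. ASG13709 stood at 1095.4 RPKM in ovary, was listed at 0 in testis and did not exceed 0.4 RPKM in the 4 somatic libraries, and ASG15421 stood at 995.8 RPKM in ovary and did not exceed 0.7 RPKM in those libraries. In the opposite direction, 897 genes reached 5 RPKM in an adult somatic library and stayed under 1 RPKM in both gonads.

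The same rule was applied to every other choice of 2 among the 6 adult libraries. Testis with ovary gave the highest of the 15 counts, 885, followed by testis with intestine (264) and testis with male carcass (252), and the lowest was muscle with female carcass (25). With the median percentages of testis-led and larva-led genes subtracted from ovary, the lead of testis with ovary over the other pairs with testis was nearly gone. The counts were then 842 for testis with ovary, 826 for testis with male carcass, 712 for testis with intestine, 685 for testis with female carcass and 657 for testis with muscle. Lowering ovary alone can only raise the counts of testis alone or with a somatic library, and can only lower that of testis with ovary. The subtracted 3.60% also exceeds the ovary percentage of many testis-led genes (lower quartile 2.80%). These counts are also not like with like, because nothing was subtracted from male carcass and intestine. Testis-led genes stood there at medians of 0.67% and 0.33%, which can raise the counts of 826 and 712. Counts for pairs that part the 3 libraries containing muscle are held down by the tissue they share. Taken alone against the other 5 adult libraries, testis had 215 restricted genes, ovary 72, intestine 37, male carcass 24, female carcass 6 and muscle 5. After the subtraction testis had 643 and ovary 40. The count of 885 depended on the level allowed in soma, being 452 at under 0.5 RPKM and 1402 at under 2 RPKM.

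The most abundant testis transcripts did not meet the rule. Of 130 testis-led genes at 500 RPKM or more, 0 were gonad-restricted, because all 130 stood at 1 RPKM or more in male carcass and 111 did so in intestine. Their median level in male carcass was 0.67% of that in testis, in intestine 0.33% and in female carcass 0.024%. Where a somatic level of up to 2% of the gonad level was also allowed, 115 of the 130 qualified and the total rose to 1290 genes, a rule chosen after the data were seen.

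**Figure D2:**
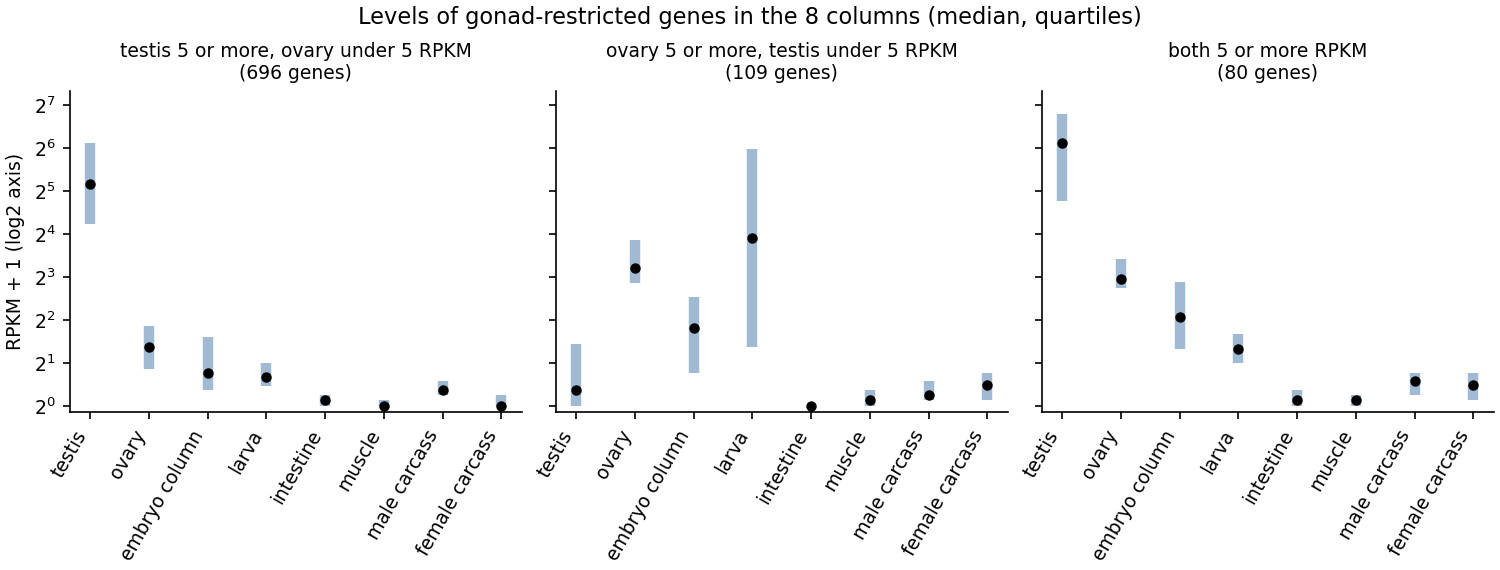
Points are medians and bars the quartiles of RPKM + 1 (log2 axis) in each column for the gonad-restricted genes, split by their level in testis and ovary. The 696 testis genes have a median of 35 RPKM in testis and 1.6 in ovary, and the 109 ovary genes have a higher median in larva (14 RPKM) than in ovary (8.3 RPKM).

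Gonad-restricted genes were also followed into embryo and larva. Of the 885 genes, 448 (50.6%) were at 1 RPKM or more in the embryo column, 358 (40.5%) in larva and 304 in neither. Both shares lay below those of all genes, 79.1% in the embryo column and 81.2% in larva. The limit of 1 RPKM in soma removes broadly expressed genes, so lower shares are partly built in. The 80 genes of both gonads were the most often detected in embryo, 68 of them at 1 RPKM or more, against 303 of the 696 testis genes and 77 of the 109 ovary genes. The 68 make up 85%, near the share of all genes, and the testis and ovary genes lay below that share. In ovary itself 670 of the 885 were detected. Testis-led genes stood in ovary at a median of 3.60% of their testis level and in larva at 1.20%. Larva-led genes stood in ovary at a median of 8.73% and ovary-led genes in larva at 2.37%. After these percentages were subtracted, 223 of the 885 genes were at 1 RPKM or more in ovary and 168 in larva, 66 of the 109 ovary genes still had 5 RPKM or more in ovary, and 33 of the 80 genes of both gonads did.

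Genes shared by both gonads were counted by enrichment. In total 383 genes were gonad-enriched, with both testis and ovary at least 4-fold above the highest somatic value on the log2(RPKM + 1) scale, and 198 were at least 4-fold lower in both gonads than in every somatic library. Of the gonad-enriched genes, 251 (65.5%) were at 5 RPKM or more in embryo, against 61.2% of all genes and 89.5% of the genes at that level in ovary. In larva 200 (52.2%) were, against 58.9% of all genes and 84.6% of the genes at 5 RPKM or more in ovary. ASG10668 had 401.4 RPKM in testis and 482.5 in ovary against at most 4.1 in soma, and ASG10951 had 54.8 and 111.9 against at most 0.5. On the somatic side, ASG02187 was listed at 0 in both gonads and ranged from 135.9 RPKM in muscle to 457.4 in intestine, and ASG12533 ranged from 456.1 to 6761.4 RPKM against at most 5.9 in a gonad. The gonad-enriched count fell to 181 after the subtraction described above and to 127 with scaling by the median of ratios, and it was 637 without female carcass. For the other pairs of adult libraries the same rule gave at most 53 genes (ovary with female carcass) as deposited and at most 55 (male with female carcass) after the subtraction.

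Testis and ovary differed at 4670 genes, 30.2% of the table, against 924 genes (5.98%) for male and female carcass. Of these, 1602 were higher in testis, with a median of 64 RPKM in testis and 2.8 in ovary, and 3068 were higher in ovary, with medians of 24.6 RPKM in ovary and 2.1 in testis. Of the testis-high genes, 24.3% reached 5 RPKM in embryo, 17.3% in male carcass, 17.1% in larva, 10.7% in intestine, 9.61% in female carcass and 7.74% in muscle, and 721 were gonad-restricted. Of the ovary-high genes, 82.5% reached 5 RPKM in embryo, 80.3% in larva, 66.3% in female carcass, 57.8% in male carcass, 49.5% in muscle and 40.1% in intestine, and 82 were gonad-restricted. Among all genes at 5 RPKM or more in ovary, the shares were higher, 89.5% in embryo and 84.6% in larva. ASG14067 (3795.5 RPKM in testis, 24.9 in ovary, log2 ratio 7.20) and ASG10122 (1002.3 and 6 RPKM, log2 ratio 7.16) led the testis side, and both were also present in male carcass, at 688.9 and 188.1 RPKM. ASG02506 (2.5 RPKM in testis, 16997.2 in ovary, log2 ratio -12.25) and ASG11339 (listed at 0 in testis, 2519.3 RPKM in ovary) led the ovary side. The split of 34.3% higher in testis turned to 70.8% (2327 higher in testis, 961 higher in ovary) with scaling by the median of ratios, which moved the median log2 ratio of all genes from -0.83 to 0.0. It was also 50.4% with a pseudocount of 5 and 54.2% at a log2 threshold of 3, and 42.6% after the subtraction.

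**Figure D3:**
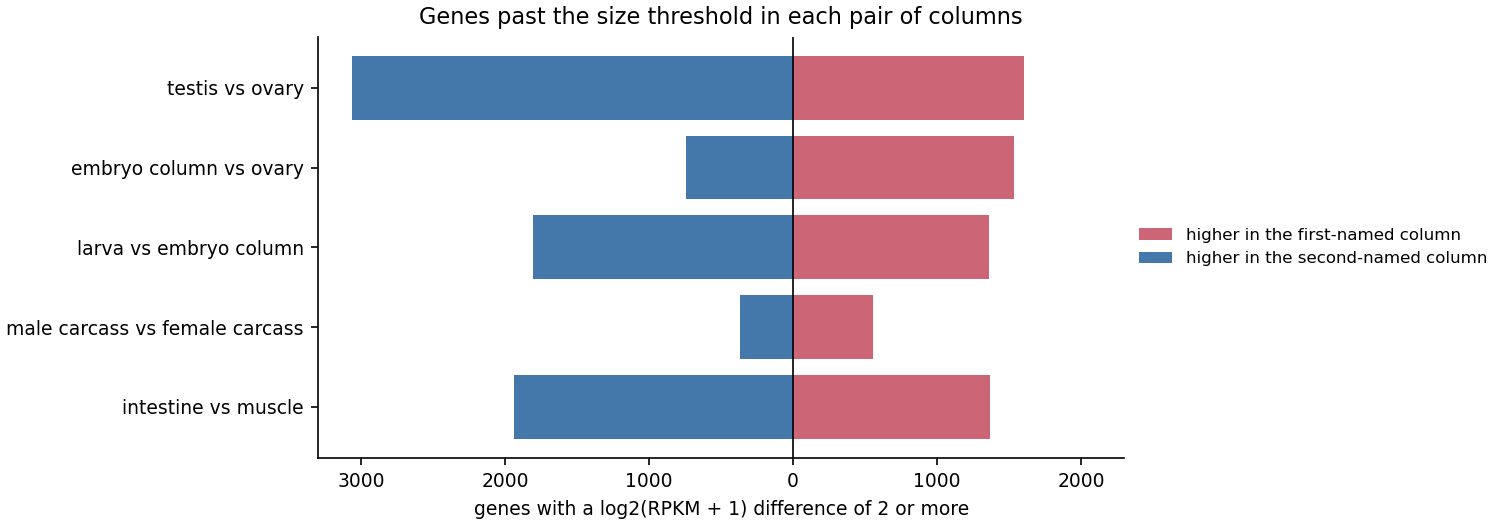
Bars give the number of genes with a log2(RPKM + 1) difference of 2 or more in each pair of columns, to the right for genes higher in the first-named column and to the left for those higher in the second. Testis against ovary gives 1602 and 3068 genes, and male against female carcass, the pair of like tissue, gives 554 and 370. With scaling by the median of ratios the larger side changes for testis against ovary (2327 and 961), embryo against ovary (614 and 900) and larva against embryo (1497 and 932).

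Early embryo was compared with ovary, whose library is from the germinal zone. Whether that library stands for the RNA an embryo inherits was not tested. The embryo column was higher at 1534 genes and lower at 748, together 14.8% of the table. Most ovary transcripts were present in embryo, where 7810 of the 8722 genes at 5 RPKM or more in ovary also reached that level. Genes higher in embryo had medians of 33.8 RPKM in embryo and 3.5 in ovary. By the same threshold 722 of the 1534 were lower in larva than in embryo, against 1809 of all 15446 genes. Both comparisons use the same embryo column, so a high value there puts a gene on both lists. The overlap is therefore partly built in and does not by itself show a rise and fall. ASG00628 (354.2 RPKM in embryo) was listed at 0 in ovary and stood at 1 in larva. ASG01787 stood at 339.9 RPKM in embryo, 0.4 in ovary and 2 in larva. Genes lower in embryo had medians of 25.8 RPKM in ovary and 1.4 in embryo. They included ASG02506, at 4.3 RPKM in embryo against 16997.2 in ovary, and ASG05811, at 1.9 against 6444.3. The median log2 ratio of all genes was 0.32 in favour of embryo, and the split of 67.2% higher in embryo became 40.6% (614 and 900 genes) with scaling by the median of ratios, 45.0% (803 and 981) with scaling by the upper quartile and 85.0% (2410 and 424) after the subtraction from ovary.

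Larva differed from embryo at 3170 genes (20.5%). Larva was higher at 1361 genes, with medians of 23.8 RPKM in larva and 1.1 in embryo, and lower at 1809, with medians of 2.9 and 33.8 RPKM. Of the larva-high genes, 870 had their highest level of all 8 columns in larva. ASG01436 (3927 RPKM in larva, 0.2 in embryo, log2 ratio 11.68) and ASG07223 (1108.3 and 0.2 RPKM, log2 ratio 9.85) were the 2 largest. Both also had values in ovary, 315.4 and 96.8 RPKM, near the 8.73% median of larva-led genes there. ASG00628 and ASG01787 were the 2 largest in the opposite direction. The split of 42.9% higher in larva became 61.6% (1497 and 932 genes) with scaling by the median of ratios and 58.5% (1627 and 1152) with scaling by the upper quartile.

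Male and female carcass, listed with the same tissues, differed at 554 genes higher in male and 370 higher in female. At a log2 threshold of 1 the larger side turned, with 1689 higher in male and 1881 higher in female. Among genes of 10 RPKM or more in either, the median absolute log2 difference was 0.59 and 95% of genes lay within 3.00. By that range, 27.9% of genes lay beyond it for testis against ovary, 33.7% for intestine against muscle, 14.4% for larva against embryo and 8.79% for embryo against ovary. Of all 15446 genes, 9449 reached 5 RPKM in embryo, 9096 in larva, 8722 in ovary, 6593 in testis, 5851 in muscle and 5489 in intestine. Male-high genes had a median of 24.5 RPKM in male carcass and 1.3 in female carcass. Of these, 268 (48.4%) reached 5 RPKM in larva, 239 (43.1%) in ovary, 234 (42.2%) in intestine and 232 (41.9%) in testis. In muscle 195 (35.2%) did and in embryo 189 (34.1%). Among these columns only the intestine share lay above that of all genes. Female-high genes had medians of 19.9 RPKM in female carcass and 2.2 in male carcass. Of these, 276 (74.6%) reached 5 RPKM in embryo, 249 (67.3%) in ovary and 170 (45.9%) in testis, above the shares of all genes. In larva 176 (47.6%) did, in muscle 135 (36.5%) and in intestine 64 (17.3%), below those shares. ASG05169 stood at 1759.8 RPKM in male carcass, 2.5 in female carcass and 12019.1 in testis, whereas ASG07806 stood at 732.2 RPKM in male carcass, 0.7 in female carcass and was listed at 0 in testis. ASG14205 (1681.4 RPKM in female carcass, 8.7 in male) and ASG06794 (4674.5 and 33.6 RPKM) were the largest on the female side, and both were also present in intestine, at 417.3 and 3547.9 RPKM.

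Intestine and muscle differed at 3309 genes (21.4%), with 1371 higher in intestine and 1938 higher in muscle. Intestine-high genes had medians of 35.4 RPKM in intestine and 2.4 in muscle. Muscle-high genes had medians of 22.5 RPKM in muscle and 0.2 in intestine, and 78.4% of them reached 5 RPKM in female carcass and 75.7% in male carcass. ASG05529 stood at 5945.6 RPKM in intestine and 14.3 in muscle, and also at 7869.3 in male carcass but 80.9 in female carcass. ASG10515 stood at 213.6 RPKM in intestine and was listed at 0 in muscle. ASG01479, at 17564.6 RPKM in muscle and 1.7 in intestine, and ASG05179, at 7864.4 and 0.6 RPKM, led the muscle side. Intestine-led genes were present in muscle at a median of 3.31% of their intestinal level, in male carcass at 7.45% and in female carcass at 10.1%.

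Expression confined largely to a single column was commonest in testis. Of 13518 genes at 5 RPKM or more in some column, 532 (3.94%) had a tau of at least 0.9. Their highest column was testis for 331, larva for 96, embryo for 34, intestine for 29, male carcass for 28, ovary for 7, muscle for 6 and female carcass for 1. Muscle and the carcasses share tissue by their labels, which can lower their own counts by construction. With muscle and both carcasses averaged the total was 541, little changed. The total was 1024 after the subtraction from ovary and larva, with 716 for testis, 192 for larva and 14 for ovary, and 45 with a pseudocount of 0.1. Lower ovary and larva values raise the testis count by construction.

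The level of testis-led genes in the other columns was measured over a wide range of testis expression. For 821 testis-led genes at 50 RPKM or more, the median percentage in ovary stayed between 3.51% and 3.83% over 5 bins of testis level, and in larva between 1.16% and 1.45%. In male carcass it stayed between 0.63% and 0.81%, and in intestine between 0.22% and 0.42%. In the embryo column it ran from 0.071% in the highest bin to 1.92% in the lowest, and in female carcass from 0.014% to 0.22%. In the lowest bin (50 to 100 RPKM in testis) the intestine and female carcass medians stand for values near the rounding step of 0.1 RPKM. Their course at low testis levels is therefore uncertain. The highest testis gene, ASG12930, stood at 1316.7 RPKM in ovary, 366.7 in larva, 312.6 in male carcass, 296.5 in intestine, 8.7 in embryo and 0.7 in female carcass.

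**Figure D4:**
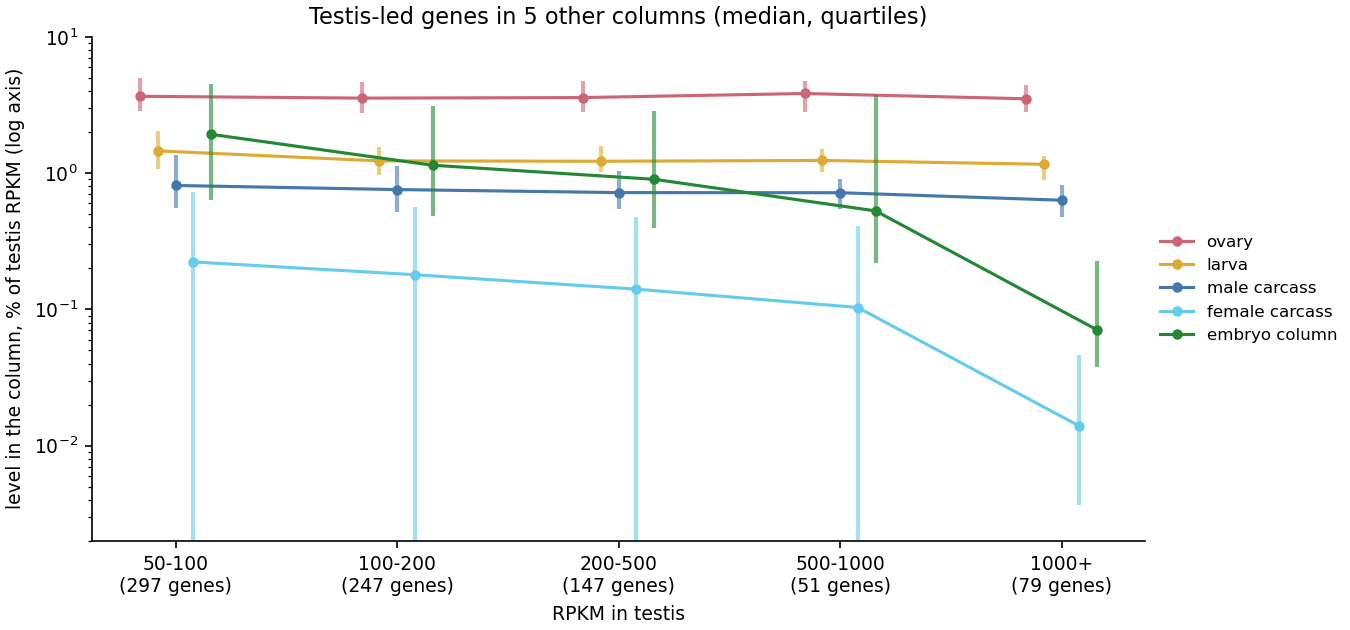
Points are median levels of testis-led genes in 5 other columns as a percentage of their testis RPKM (log axis) in 5 bins of testis RPKM, and vertical bars are quartiles (those reaching 0 are cut at the lower edge of the axis). Ovary stays between 3.51% and 3.83% and larva between 1.16% and 1.45%, while the embryo column falls from 1.92% to 0.071%.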

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

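The subtraction of led-gene percentages, the embryo-column comparisons with their named genes, the counts in ovary and larva and the count restricted to testis were chosen after seeing the data. Over 24 counts, 145 alternatives were computed, of which 79 stayed within 1.5 times of the reported count and 66 moved further. The cause was not tested except where a stricter or looser threshold, or values lowered by the subtraction, move a count by construction. The planned comparisons of timed embryos were not run. Of 100 alternatives for 20 named log2 ratios, 83 moved by less than 1.39 (the SD of log2 differences between male and female carcass, a wide tolerance), 17 moved further and 0 changed sign. The named ratios were picked as the largest, so the lack of sign changes is no evidence of stability. With 1 library per tissue no paired or left-out replicate analysis exists, and unknown depth leaves low values without an interval.

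With a minimum of 5 RPKM, 6593 genes were detected in testis, 5489 in intestine, 5851 in muscle, 7310 in male carcass and 7484 in female carcass. Gonad-restricted genes numbered 452 at under 0.5 RPKM in soma, 1402 at under 2 RPKM and 527 with larva added to soma. After the subtraction, 223 of them reached 1 RPKM in ovary and 168 in larva, 643 genes were restricted to testis among adult libraries, gonad-enriched genes numbered 181, embryo was higher than ovary at 2410 genes and lower at 424, and 1024 genes were tissue-specific. Tissue-specific genes numbered 1837 at a tau of 0.8.

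With a pseudocount of 0.1 there were 937 gonad-enriched genes, 5416 higher in ovary than testis, 2508 higher and 1584 lower in embryo than ovary, 2206 higher in larva than embryo, 1549 higher in male and 1043 in female carcass, 2237 higher in intestine and 3516 in muscle, and 45 tissue-specific. With a pseudocount of 5 these were 122 gonad-enriched, 1245 higher in ovary, 694 higher and 360 lower in embryo, 653 higher and 929 lower in larva, 255 male and 130 female, and 810 intestine and 1037 muscle.

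At a log2 threshold of 1 there were 1444 gonad-enriched genes, 7007 higher in ovary, 4608 higher and 2111 lower in embryo, 2928 higher and 4448 lower in larva, 1689 male and 1881 female, and 3044 intestine and 3354 muscle. At a threshold of 3 these were 51 gonad-enriched, 1080 higher in ovary, 487 higher and 326 lower in embryo, 673 higher and 727 lower in larva, 222 male and 95 female, and 754 intestine and 1252 muscle.

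Scaling by the upper quartile gave 220 gonad-enriched genes, 803 higher in embryo than ovary and 1152 lower in larva than embryo. Scaling by the median of ratios gave 127, 614 and 932 for these, and 961 genes higher in ovary than testis. Scaling to an equal sum gave 637 gonad-enriched genes and 4696 higher in ovary than testis. Without the female carcass library 637 genes were gonad-enriched.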

Other observations

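The tests of testis-led, ovary-led and larva-led genes in other columns, of the carcasses and of consecutive identifiers against shuffles were chosen after the results were seen, and those of soma-restricted genes along the identifiers and of testis levels of consecutive genes were set down beforehand. Beyond the comparisons above, expression confined to 1 of the 8 columns (5 RPKM or more there, under 1 RPKM in the other 7) was found for 138 testis genes, 47 larva genes, 28 embryo genes, 27 intestine genes, 17 male carcass genes, 4 muscle genes, 2 ovary genes and 1 female carcass gene. With the subtraction from ovary and larva these were 359 for testis, 123 for larva and 6 for ovary, and lower ovary and larva values can only raise the testis count. Male carcass thus had 17 genes of its own while muscle and female carcass had 4 and 1, although the labels list muscle in all 3. The male-high carcass genes had their highest level in male carcass in 310 of 554 cases and in testis in 126, and the female-high genes had theirs in embryo in 127 of 370, in ovary in 111 and in female carcass in 66.

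A first pattern is the near fixed percentage at which testis-led genes stand in ovary and in larva. If the ovary values held testis RNA or reads at 1 share, the slope of log2 ovary on log2 testis level would be near 1, and over 821 genes it was 0.97 (bootstrap 95% interval 0.95 to 1.00), while embryo, under the same selection of genes, gave 0.33 (0.26 to 0.41). The slope was 0.92 in larva (0.89 to 0.95, an interval below 1), 0.96 in male carcass (0.92 to 1.01) and 1.07 in intestine (1.00 to 1.14), the last with an upper quartile 4.80 times the lower one, so a slope near 1 is not special to ovary. For the slopes, values listed at 0 were set to 0.05 RPKM, which touches columns with low values such as intestine. The spread between quartiles was narrow in ovary, an upper quartile 1.69 times the lower one against 9.0 times in embryo. This argues against expression set gene by gene as the main source for the genes between the quartiles. It does not do so for the genes outside them. A candidate explanation is that some testis material or reads entered the ovary and larva values, with male carcass open in the same way (upper quartile 2.15 times the lower one). In intestine the wider spread of 4.80 times leaves expression set gene by gene open as well. Larva material or reads may likewise have entered the ovary values (slope 1.00 over 170 larva-led genes). Ovary-led genes in larva had a slope of 0.81 (0.74 to 0.88) and bin medians from 2.26% to 5.14%, short of a fixed share. Low expression under shared regulation was tested only through the spread of the ovary percentages. Apart from noise, a single share cannot exceed the lowest percentage. Among 130 testis-led genes at 500 RPKM or more, the ovary percentage had a 5th percentile of 1.92% and a 95th of 8.04%. ASG14067 and ASG10122, picked as the largest ratios, stood lower, at 24.9 and 6 RPKM in ovary against 3795.5 and 1002.3 in testis. The subtracted median of 3.60% set these 2 genes to 0 in ovary.

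A second pattern is the difference between male and female carcass. RNA of the testis germinal zone left in the male carcass as the whole cause is argued against by 419 of the 554 male-high genes. Their excess over female carcass was above their entire testis level, for 256 of them by over 20-fold. For the other 135 that bound allows any share of testis RNA, and the excess lay within 0.67% of the testis level (the median of testis-led genes in male carcass) for 40 of the 554 and within 3.78% (their 95th percentile) for 96. RNA of the ovary germinal zone or embryo left in the female carcass as the whole cause is argued against by 103 of the 370 female-high genes. Their excess was above both levels. For 38 of the 370 the excess lay within the median percentages of ovary-led and embryo-led genes in female carcass (3.63% and 5.46%). It lay within their 95th percentiles (18.6% and 12%) for 191, so how much of that side carried-over RNA makes up stays open. Parts of the reproductive tract outside the germinal zones had no library here, so RNA left from them is not bounded on either side. Sex itself, the makeup of the dissected tissue and differences between single animals or preparations cannot be separated with 1 library each.

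The last pattern is the order of the gene identifiers, whose meaning is not given in the sources used here. Gonad-restricted genes had consecutive numbers in 160 cases, against a mean of 50.7 and a highest count of 72 in 1000 shuffles, which argues against numbers unrelated to expression. Soma-restricted genes did so in 163 cases against a highest of 78, so the neighbourhood is not special to the gonads, and over all genes the mean profile correlation was 0.34 for consecutive numbers and 0.16 at a distance of 1000. The share of gonad-restricted genes rose from 3.92% in the first of 3 equal parts of the numbers to 8.08% in the last. That of soma-restricted genes went from 5.77% to 5.15% (last over first 0.89). This argues against poorer gene models at high numbers that would raise both classes alike. Poor models seen mainly in testis reads would raise only the first class and could not be examined without an annotation. Near-identical copies next to each other that share reads cannot be told apart from co-regulated neighbours without sequences, since consecutive gonad-restricted genes differed in testis level by a median of 1.28 on the log2 scale against 1.65 (1.35 to 1.98) for random pairs, as both would give.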
